A study of Homo sapiens with 2 samples.

How the data were processed

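RNA was measured in 2 libraries of TPC-1, a human papillary thyroid carcinoma cell line that carries a fusion of CCDC6 with the receptor tyrosine kinase RET. One library came from cells transfected with a control siRNA and the other from cells transfected with an siRNA against XPR1. Per the labels' protocols, RNA was extracted with RNeasy Plus kits and libraries were made with the TruSeq RNA Library Prep Kit v2. That kit does not mark strand, so reads of a gene and of a gene that overlaps it on the other strand cannot be told apart. The submitters' processing notes list FastQC, MultiQC, Trimmomatic 0.38, featureCounts 2.0.0 and the GRCh38 genome build, without their order. The aligner, the annotation release, the siRNA sequences and the time after transfection are not given in the sources used here.

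The authors deposited TPM values, a length-corrected share of transcripts, for 58884 Ensembl genes in 1 table, which holds both libraries. Each column of the deposited TPM values sums to 1000000, so values are relative to all transcripts of the same library, and no further scaling between libraries is recorded. Mitochondrial genes held 27.3% of the TPM in the control library and 27.5% in the XPR1-siRNA library. Gene symbols were taken from a table of gene identifiers, which matched 58472 of the 58884 identifiers, and otherwise from GENCODE 29 on GRCh38. Gene lengths, gene types and coordinates came from GENCODE 29, which held 58611 of the identifiers. In all, 58876 identifiers had a symbol or a name.

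TPM values as such keep no read numbers. Here, the product of TPM and gene length (the union of a gene's exons) fell on whole multiples of a step of 237.0 in the control library and 246.3 in the XPR1-siRNA library. Dividing by that step gave a value within 0.01 of a whole number for 92.3% and 92.4% of genes with up to 10 reads, against 2.0% that chance would give. Over all genes above 0 it did so for 71.9% and 71.3%, and over protein-coding genes for only 55.3% and 55.0%. Whether the authors' gene lengths differ from GENCODE 29 for the remainder was not tested. By this reckoning the libraries held about 15780000 and 15150000 counted reads. In a gene of 2000 exonic bases 1 read is worth 0.118 and 0.123 TPM, and the limit that a count of 0 allows (3 reads) is 0.355 and 0.369 TPM. The recovered reads gave 95% Clopper-Pearson intervals for the ratio of the 2 libraries. They are approximate for genes whose reads did not come out whole. Of the 110 genes that the rule below names, only 42 had whole reads in both libraries. The recovery was chosen after seeing the data. Intervals and floors cover counting error only. They can understate even that, since reads without molecular identifiers are not independent molecules.

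With 1 library per group, no test of the conditions can be made and no p-value is given. Differences are on the log2(TPM + 1) scale, which understates those of low genes, and folds are ratios of TPM. The plan had assumed counts. It named a comparison of log2(value + 1) for values without counts, and this was used as the main comparison for all results. Genes with a mean TPM of at least 1 over the 2 libraries were compared, and those at least 2-fold apart on that scale were counted.

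Before the data were examined, 44 gene lists were fixed, holding 1359 genes, of which 1357 were in the table. They comprise pathways, stress and growth responses, thyroid genes and markers of other cell types, and 66 of the genes are in more than 1 list. For each of the 40 lists with at least 5 members at a mean TPM of at least 1, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart below percentile 2.5 or above percentile 97.5. With 40 lists, 2.0 would do so by chance if genes varied independently, which genes of 1 pathway do not. The percentile describes these libraries and is not a p-value. Members at least 1.5-fold apart on the log2(TPM + 1) scale were counted.

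The rule for named genes was fixed at the same time. It takes XPR1, the 12 highest and 12 lowest ratios among protein-coding genes with a symbol and a mean TPM of at least 10, and the 4 members farthest in the list's direction for every list that stands apart. It also takes the 4 members with the largest difference in either direction from the phosphate, thyroid, ERK, p53 and receptor tyrosine kinase lists. Some genes that the rule takes are not reported here. Other genes named in the text were chosen after their values were seen, and are marked so.

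Alternatives were median-of-ratios, upper-quartile and trimmed-mean scaling (30% of ratios and 5% of levels trimmed at each end), other floors and pseudocounts, thinning of the deeper library, removal of a lowess trend on level or on gene length (fraction 0.3), protein-coding genes only, list means, matching on length, and the recovered reads. The method was tested on simulated data, with reads drawn for the real genes at the real depths. Of the genes set 4.0-fold higher and lower, 94.0% and 78.0% were found at least 2-fold apart, and of those set 2.5-fold higher and lower, 80.0% and 70.0%. Of 15755 genes left unchanged, 3.72% came out at least 2-fold apart through counting error alone. Of 200 random lists in those simulated data, 5.5% stood apart, and all of 50 lists shifted by 0.5 on the log2 scale were found. Apart from genes changed on purpose, the simulated libraries differed by counting error only. The real log2 ratios had a standard deviation of 0.875, so the share of shifted lists found does not carry over to the real lists. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.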

Results

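To ask how TPC-1 thyroid carcinoma cells respond to loss of XPR1, RNA was sequenced after transfection with a control siRNA or an siRNA against XPR1, with 1 library each. XPR1, the xenotropic and polytropic retrovirus receptor, is the phosphate exporter of human cells. The control library listed 23659 genes above 0 TPM and the XPR1-siRNA library 23489, from about 15780000 and 15150000 counted reads. There was no replicate, so no difference below has a replicate check. Higher and lower describe these 2 libraries, and the intervals given cover counting error only.

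XPR1 transcript was 39.2 TPM in the control library and 5.31 TPM in the XPR1-siRNA library, leaving 13.5% of the control level (95% Clopper-Pearson interval 11.6% to 15.8%, from 1474 and 192 reads). XPR1 (ENSG00000143324) lies on chromosome 1 from 180632004 to 180890251 on the plus strand of GRCh38, and the value covers the 8903 bases of its exons. The difference of -2.67 on the log2(TPM + 1) scale ranked 43rd from the lowest among 8264 protein-coding genes with a mean TPM of at least 10.

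The libraries differed widely beyond XPR1. The lowest ratios included those of CSF3, PTGS2, MMP1 and IL1A, and the highest those of FLG, CD24, THBS1 and MAMDC2. Of 16319 genes with a mean TPM of at least 1, 1699 were at least 2-fold higher and 1398 at least 2-fold lower in the XPR1-siRNA library. Counting error can place genes past this threshold, and 1205 and 840 also had a counting interval that excluded equality. Among the 11698 protein-coding genes, 1023 were higher and 535 lower, so higher genes made up 65.7% of those, against 54.9% of all genes. The excess among all genes depended on the scaling, since upper-quartile scaling gave 1472 higher and 1523 lower. The median log2 ratio of all expressed genes was 0.05.

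Among the lowest ratios, CSF3 (ENSG00000108342, chromosome 17, 40015361 to 40017813), the granulocyte colony-stimulating factor, was 392.1 TPM in control and 1.66 TPM after XPR1 siRNA, 236-fold lower (143 to 421). PTGS2 (chromosome 1, 186671791 to 186680427), the inducible cyclooxygenase, was 375.0 and 2.57 TPM, and the collagenase MMP1 454.1 and 3.87 TPM. The interleukin IL1A (chromosome 2, 112773915 to 112784590) was 716.0 and 9.86 TPM, 72.6-fold lower (58.7 to 91.1), and its neighbour IL1B 74.2 and 1.35 TPM. CSF2 was 17.6-fold lower and the chemokine CCL20 21.9-fold lower. The signalling adaptor TRAF1 was 24.3-fold lower, the protease inhibitor SERPINB7 19.6-fold, and the endothelial lipase LIPG 32.7-fold. TCIM and the decoy receptor IL13RA2 were 84.4 and 59.2 TPM in control and below 1 TPM after XPR1 siRNA, so their folds rest on few reads.

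Among the highest ratios, FLG (ENSG00000143631, chromosome 1, 152302175 to 152325203), which encodes the epidermal protein filaggrin, was 6.93 TPM in control and 186.1 TPM after XPR1 siRNA, 26.8-fold higher (24.2 to 29.8). The surface glycoprotein CD24 (chromosome 6, 106969831 to 106975627), which has near-identical copies, was 14.5 and 353.1 TPM, and the matrix protein THBS1 18.7 and 316.0 TPM. The growth factor TGFB2 was 13.9-fold higher, the proteoglycan SDC2 10.4-fold and the collagen COL12A1 10.4-fold. TUBA1A was 11.9-fold higher, a value that depends on how reads of near-identical tubulin genes were counted. MAMDC2, CRACD, OLFML2A, LRRN4 and KCTD4 were between 11.5-fold and 20.6-fold higher.

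**Figure D1:**
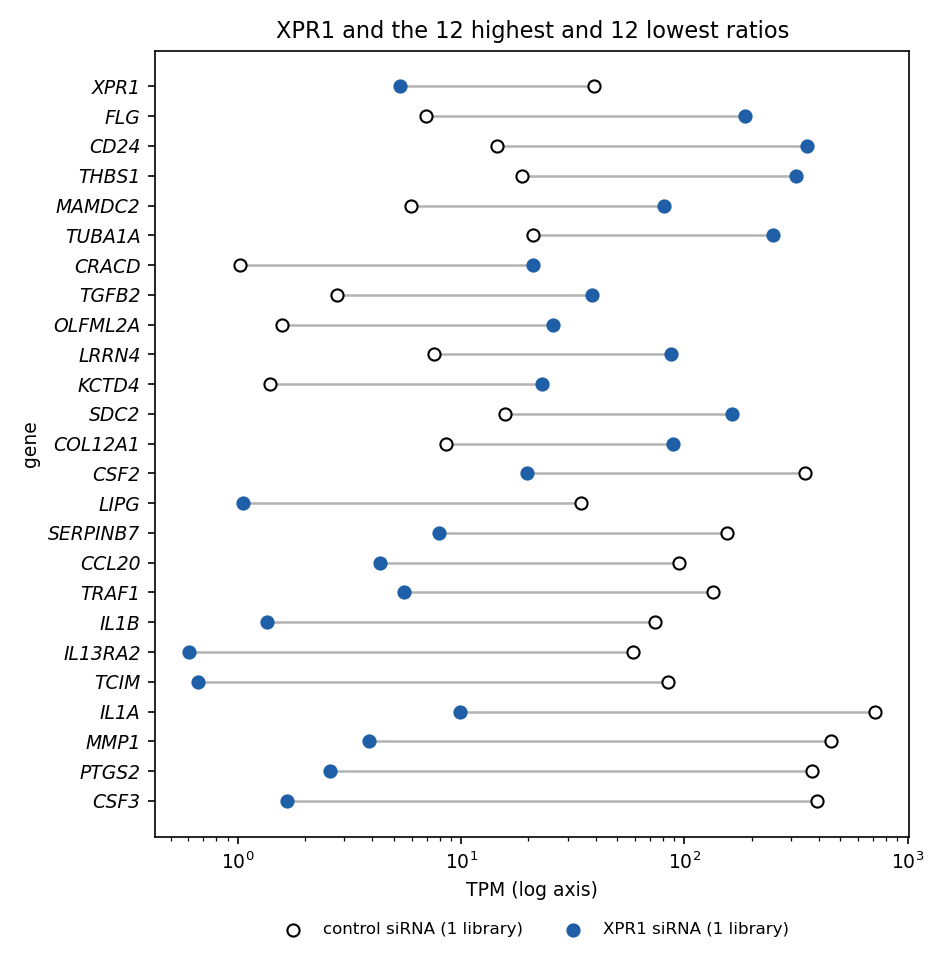
TPM (log axis) of XPR1 and of the 12 protein-coding genes with the highest and the 12 with the lowest ratios at a mean TPM of at least 10, each library as 1 point. XPR1 spans 39.2 to 5.31 TPM, while CSF3 spans 392.1 to 1.66 TPM and FLG 6.93 to 186.1 TPM.

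Of the 40 gene lists tested, 11 stood above and 9 below random lists matched on expression, and 20 did not stand apart. The NF-kB and cytokine list had the lowest median, at -1.89 on the log2 scale (percentile 0.0). Of its 37 expressed members, 32 were at least 1.5-fold lower and 3 were higher. Besides CSF3, PTGS2, IL1A and IL1B, which the rule names, genes chosen after their values were seen include CXCL8, a neutrophil chemokine, at 7564 and 901.1 TPM, IL6 at 1132 and 200.5 TPM, and CCL5 at 704.3 and 75.1 TPM. The 3 higher members, named after their values were seen, were CCL2 (191.4 and 386.3 TPM), IL32 and CD83.

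Genes that are transcribed downstream of ERK signalling were lower, with 21 of 29 at least 1.5-fold lower, 2 higher and a median of -1.01 (percentile 0.0). PHLDA1 was 767.6 and 133.5 TPM, MAFF 39.1 and 8.65 TPM, and EGR1 120.6 and 28.3 TPM, and VGF was 5.57 and 0.368 TPM. The members that were higher, named after their values were seen, were EPHA4 and ETV1. Of 23 immediate early genes, 18 were lower and 1, BTG2, was higher, with a median of -1.19 (percentile 0.0). FOSB was 8.14-fold lower, NR4A3 14.7-fold and ATF3 4.69-fold. The list of RET, other receptor tyrosine kinases and ligands did not stand apart (median 0.25, percentile 91.3, and 0.10 with genes down to 0.1 TPM), with 8 of 24 higher and 6 lower. The EGF receptor ligands HBEGF and EREG were 15.9-fold and 4.08-fold lower, while FGFR4 was 6.24-fold and GFRA1, a co-receptor of RET, 4.30-fold higher. RET itself, chosen after its value was seen, was 34.7 and 34.5 TPM.

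Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, were lower as a group. Of 39 expressed members, 33 were at least 1.5-fold lower and 1 higher, with a median of -1.55 (percentile 0.0). DDIT3, which encodes CHOP, was 67.45 TPM in control and 5.84 TPM after XPR1 siRNA, 11.55-fold lower (7.995 to 17.24). PPP1R15A, which restarts translation after stress, was 8.30-fold lower, the glutathione-degrading enzyme CHAC1 8.37-fold, and SESN2 6.55-fold. Chaperones and targets of ATF6 and XBP1 were closer to control, with a median of -0.18 (percentile 1.47) and 29 of 38 members within 1.5-fold, 4 higher and 5 lower. Among the lower, ERN1 was 4.66-fold lower, XBP1 2.82-fold, DNAJB9 2.74-fold, and HSPA5, the main chaperone of the endoplasmic reticulum, 1.73-fold. This list no longer stood apart when its mean was used (percentile 18.5) or a gene length trend was removed (3.39).

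Cell cycle genes were higher in the XPR1-siRNA library. Of 51 genes of DNA replication and G1/S, 48 were at least 1.5-fold higher and none lower, with a median of 1.32 (percentile 100). PCNA, the sliding clamp of DNA polymerase, was 58.8 and 292.5 TPM, 4.98-fold higher (4.44 to 5.58), and TK1, MCM10 and GINS2 were 4.16-fold, 4.82-fold and 4.31-fold higher. Of 50 genes of G2/M and mitosis, 41 were higher and none lower by that measure, with a median of 0.98 (percentile 100). ANLN was 4.15-fold higher, the mitotic kinesin KIF20A 3.44-fold, PBK 3.16-fold and SPC25 3.24-fold. Replication-dependent histones, most of which lack poly(A) tails, did not stand apart (median 0.13, percentile 64.4), with 18 of 49 expressed.

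Sterol synthesis genes were higher as a group. Of 24 expressed members, 20 were at least 1.5-fold higher and 1, the sterol transporter STARD4 (named after its value was seen), was lower, with a median of 1.19 (percentile 100). ACAT2 was 17.5 and 94.0 TPM, and EBP and HSD17B7 were 4.75-fold and 3.75-fold higher. Fatty acid synthesis genes had a median of 0.54 (percentile 99.8), with 8 of 19 higher and none lower. ACLY was 128.6 and 456.0 TPM, ACACB 2.30 and 10.2 TPM, and ACSS2 and ELOVL6 were 3.09-fold and 2.32-fold higher. Nuclear-encoded subunits of the respiratory chain had a median of 0.44 (percentile 100), with 24 of 71 higher and none lower, among them NDUFA2, NDUFB3, COX7B and NDUFS5 at 2.18-fold to 2.62-fold. The 13 mitochondrial mRNAs did not stand apart, with a median of 0.11. Ribosome biogenesis and MYC target genes had a median of -0.37 (percentile 0.0), with 11 of 34 lower and none higher. In that list RRP12 was 2.47-fold lower and ODC1, which makes putrescine, 2.24-fold, and WDR74 and NOP58 were 1.845-fold and 1.70-fold lower. Ribosomal protein genes had a median of -0.14 (percentile 0.81), but 77 of 79 were within 1.5-fold. Among the lowest were RPL36A, RPL22 and RPL10, at 1.655-fold, 1.42-fold and 1.39-fold lower, and reads of RPL36A can be shared with near-identical copies. By its mean that list did not stand apart (percentile 18.1).

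**Figure D2:**
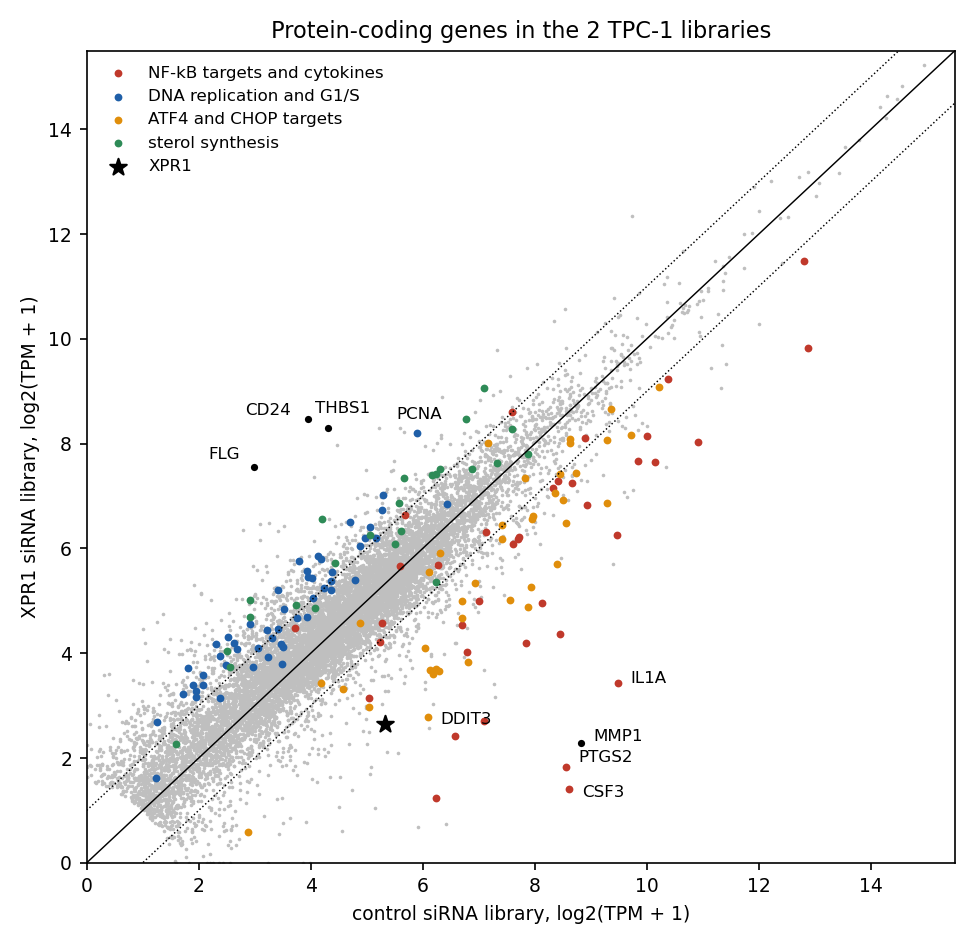
Level in the control library (x axis) against the XPR1-siRNA library (y axis), both as log2(TPM + 1), for protein-coding genes in grey with 4 gene lists in colour and XPR1 as a star. The solid line marks equality and the dotted lines a 2-fold difference. NF-kB (median -1.89) and ATF4 (median -1.55) genes lie mostly below the line, and replication (median 1.32) and sterol (median 1.19) genes mostly above it.

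The p53 target list held members on both sides. Its median was 0.32 (percentile 99.0), with 15 of 34 higher and 10 lower. TP53INP1 was 7.56 and 70.75 TPM, and FDXR, BTG2 and RPS27L were 5.49-fold, 3.47-fold and 3.01-fold higher. SESN2, which is also in the ATF4 list, and the pro-apoptotic PMAIP1 were 6.55-fold and 4.02-fold lower. CDKN1A, the p53-induced cell cycle inhibitor, chosen after its value was seen, was 118.8 and 126.9 TPM. The p53 list did not stand apart by its mean (percentile 80.3) or with a pseudocount of 5 (97.3). Of its expressed members, 9 were shared with other lists, and without shared genes the median was 0.59 (percentile 99.98).

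Interferon-stimulated genes had a median of 0.51 (percentile 99.9), with 14 of 33 higher and 3 lower. The median was 0.373 (percentile 99.8) down to a mean of 0.1 TPM and 0.275 (99.3) with a pseudocount of 5. IFIT1 was 0.770 and 10.25 TPM, IFI6 10.98 and 34.5 TPM, OAS3 9.99 and 31.6 TPM, and USP18 was 3.28-fold higher. The interferon gene IFNB1, chosen after its value was seen, had 1 read in control and none after XPR1 siRNA. Cytosolic heat shock genes had a median of 0.42 (percentile 99.4), with 8 of 24 higher and none lower. HSPB1 was 120.9 and 390.0 TPM, HSPA4L 2.996-fold higher and HSP90AA1 2.43-fold higher. HSPA1B was 2.32-fold higher, a value that depends on how reads shared with HSPA1A were counted. Metallothionein and zinc genes had a median of -0.86 (percentile 0.07), with 7 of 9 lower and 1 higher. MT2A was 2608 and 941.8 TPM, the zinc-sensing factor MTF1 2.79-fold lower, and SLC39A14 2.29-fold lower. MT1E, which has near-identical copies, was 1.99-fold lower.

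Extracellular matrix genes had a median of 0.34 (percentile 99.4), with 15 of 37 higher and 7 lower. VCAN was 80.0 and 473.1 TPM, and SPARC 372.7 and 1522 TPM, beside THBS1 and COL12A1 above. Among the lower members, chosen after its value was seen, was the laminin chain LAMB3 (2554 and 533.4 TPM). Matrix proteases and inhibitors had a median of -0.40 (percentile 0.10), with 10 of 25 higher and 10 lower. The stromelysins MMP3 and MMP10 were 13.6 and 3.77 TPM in control and were listed at 0 after XPR1 siRNA. That list did not stand apart with genes down to a mean of 0.1 TPM (percentile 15.3). Mesenchymal genes had a median of 0.46 (percentile 99.3), with 8 of 21 higher and 5 lower. The highest were MYL9, LOXL1, PDGFRB and SNAI1, at 5.81-fold, 2.225-fold, 3.15-fold and 2.13-fold, but this list did not stand apart by its mean (percentile 86.6), from 5 TPM (96.3) or with a pseudocount of 5 (96.6). Epithelial junction and keratin genes did not stand apart (median 0.14, percentile 67.5), and their median was -0.16 from 5 TPM. Wnt targets had a median of 0.60 (percentile 99.4), with 8 of 14 higher and 2 lower. BMP4 was 3.33-fold and AXIN2 3.05-fold higher. DKK1 was 6.24-fold higher (2.40 to 20.6), with 5 reads in control. TNFRSF19 rests on 1 read in control (ratio 57.2, 95% interval 9.84 to 2298). Wnt targets did not stand apart among genes with a mean of at least 5 TPM (median 0.13, percentile 64.2), with a pseudocount of 5 (97.1) or by their mean (96.5). The Wnt median was 0.93 (percentile 99.9) without genes held by several lists, and 0.815 (99.8) with the recovered reads.

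Genes of phosphate transport and sensing, apart from XPR1, did not stand apart (median 0.23, percentile 86.1), with 7 of 22 higher and 2 lower. Members with the largest differences were SLC17A5 at 18.5 and 47.8 TPM, ENPP1, which makes pyrophosphate, at 1.93 and 5.74 TPM, SLC37A4 at 5.40 and 13.6 TPM, and FGFR1 at 31.1 and 66.3 TPM. Chosen after their values were seen, the phosphate importers SLC20A1 (253.6 and 205.9 TPM) and SLC20A2 (16.05 and 12 TPM) and the XPR1 partner KIDINS220 (21.6 and 19.6 TPM) were within 1.5-fold. Of 26 thyroid differentiation genes, 12 were expressed. They had a median of 0.47 (percentile 96.6), with 6 of 12 higher and none lower by 1.5-fold. The placement depended on the setting, with a median of 0.21 (percentile 80.5) down to a mean of 0.1 TPM and 0.66 (percentile 98.8) from 5 TPM. The list also stood apart with a pseudocount of 5 (percentile 97.6), after thinning (99.1) and by its mean (97.8). The thyroid hormone transporter SLC16A10 was 3.24-fold higher, CDH16 was 3.04 and 17.1 TPM, and FHL1 1.88-fold higher. PAX8, a thyroid transcription factor chosen after its value was seen, was 588.1 and 408.6 TPM. The iodide transporter SLC5A5, also chosen after its value was seen, was 0 TPM in both libraries.

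The other lists did not stand apart in the main comparison. They were MHC class I (median 0.24), glycolysis (0.23), HIF targets (-0.12), integrins and adhesion (0.29), TGF-beta targets (0.07), YAP and TEAD targets (0.16), Notch targets (0.14), lysosome and autophagy (0.16), Golgi and vesicle traffic (0.08), NRF2 targets (0.30), nucleotide synthesis (0.12) and the RNA interference machinery (0.08, with a mean of -0.02). Apoptosis regulators had a median of 0.12 and a mean of -0.04, and senescence genes and cell cycle inhibitors a median of 0.03 and a mean of -0.41. Some of these lists stood apart under other settings. Integrins did so from 5 TPM (percentile 99.0), with the level trend removed (98.1), matched on length (98.0) and without shared genes (98.7). NRF2 targets did so from 5 TPM (98.5) and with a pseudocount of 5 (98.3), HIF targets from 5 TPM (1.96), and by their means lysosomal (99.0) and senescence (0.96) genes. Of the 21 expressed senescence genes, 9 were shared with other lists. Without these the senescence median was 0.28 (percentile 87.2). Upper-quartile scaling turned the medians of the TGF-beta (-0.009), Golgi (-0.009), RNA interference (-0.002) and senescence (-0.06) lists, and a floor of 5 TPM that of the TGF-beta list (-0.19). The senescence median also turned at a floor of 0.1 TPM (-0.024) and with the gene length trend removed (-0.015). Of the markers of other cell types, none of 20 leukocyte markers reached a mean of 1 TPM, and the highest value was 1.35 TPM. Of 15 markers each, 4 endothelial, 4 fibroblast and 3 neuroendocrine or C cell markers did so, too few for a list test. Of genes chosen after their values were seen, the fibroblast markers COL1A1 and FBLN1 were 1.04 and 6.67 TPM and 26.8 and 34.3 TPM. Chosen likewise, endothelial ROBO4 was 4.18 and 1.23 TPM, and neuroendocrine UCHL1 was 196.8 and 281.5 TPM. The highest value of any endothelial marker was 44.8 TPM.

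**Figure D3:**
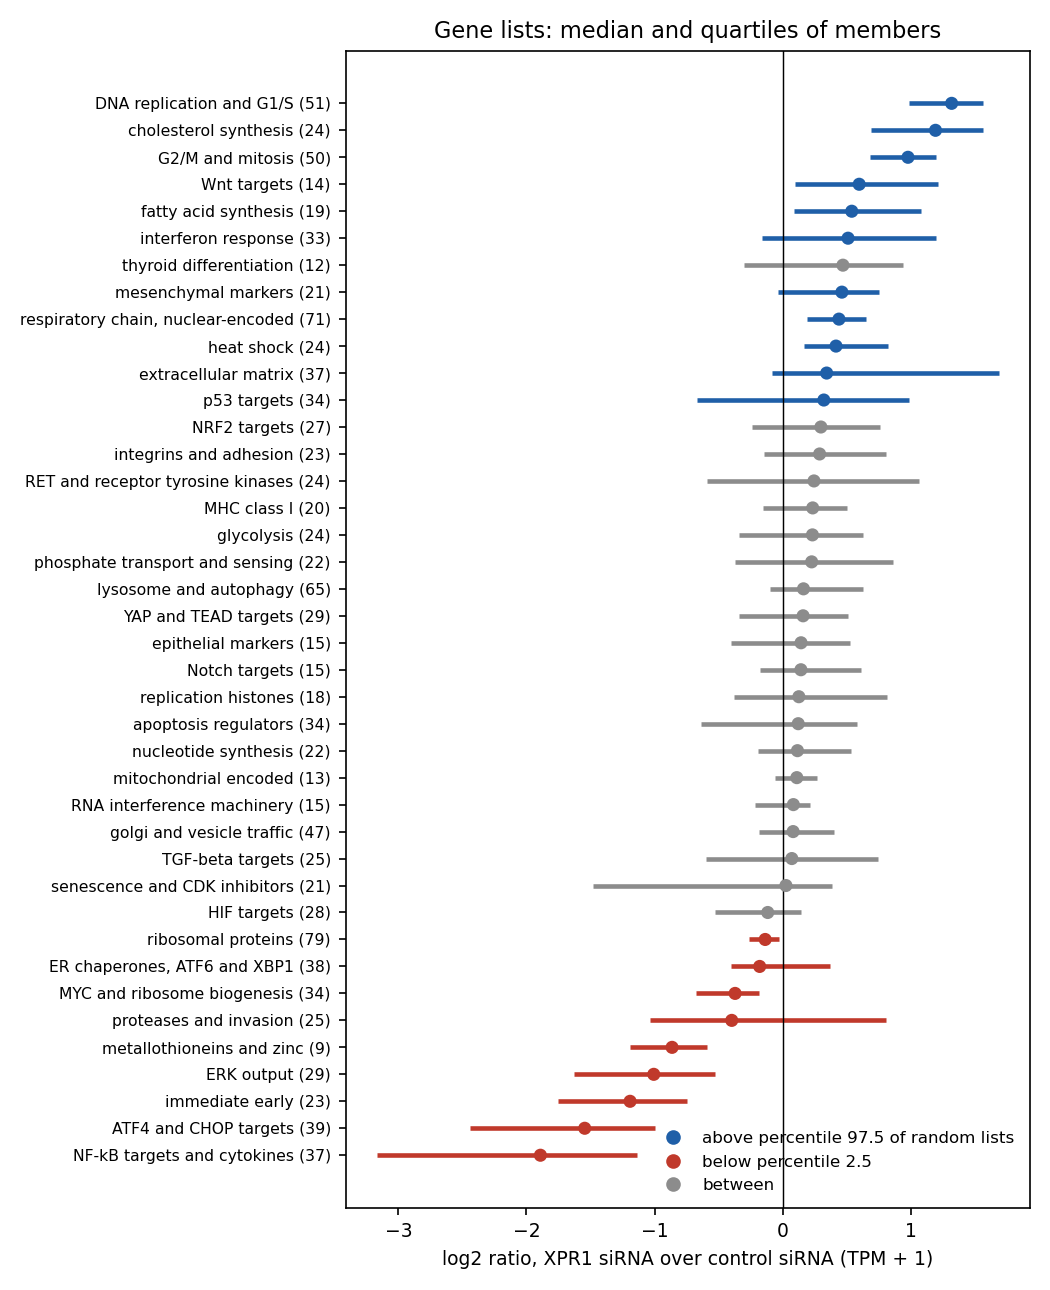
Median (points) and quartiles (bars) of the log2 ratio of XPR1 siRNA over control siRNA, on the log2(TPM + 1) scale, for the 40 gene lists with at least 5 expressed members (number in brackets). Blue marks the 11 lists that stood above and red the 9 that stood below 10000 random lists, and grey the 20 lists between.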

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

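The trimmed-mean scaling, the scaling of list medians, the recovered reads and the omission of genes held by several lists were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and no replicate could be left out. Scaling to total counts was not run separately, since TPM already sum to the same total. The scalings shifted TPM by 0.06 to 0.09 on the log2 scale before the pseudocount, and low genes by less after it. List medians moved by at most 0.09, and 4 of them turned under at least 1 scaling (TGF-beta, Golgi, RNA interference and senescence). Neither XPR1 nor any other gene named by the rule changed sign under any alternative run on it. This is a weak check, since the rule takes large differences and a change of pseudocount cannot change a sign. Of the values of the named genes other than XPR1, 121 moved beyond their counting interval and 860 did not. Upper-quartile scaling turned the excess of higher over lower genes (1472 and 1523). A pseudocount of 5 moved XPR1 to -2.101. The counts of genes at least 2-fold higher and lower moved to 855 and 634 at a floor of 5 TPM, to 577 and 530 with a pseudocount of 5, to 1023 and 535 with protein-coding genes only, and to 3541 and 2716 at a threshold of 1.5-fold. Of the placements of gene lists under the alternatives, 455 stayed on the same side of the limits, and the percentiles of the others follow. A floor of 0.1 TPM moved proteases to 15.3. A floor of 5 TPM moved mesenchymal genes to 96.3 and Wnt targets to 64.2, and moved thyroid genes to 98.8, HIF targets to 1.96, integrins to 99.0 and NRF2 targets to 98.5. A pseudocount of 5 moved p53 targets to 97.3, mesenchymal genes to 96.6 and Wnt targets to 97.1, and thyroid genes to 97.6 and NRF2 targets to 98.3. List means moved p53 targets to 80.3, the endoplasmic reticulum list to 18.5, ribosomal proteins to 18.1, mesenchymal genes to 86.6 and Wnt targets to 96.5, and moved thyroid genes to 97.8, lysosomal genes to 99.0 and senescence genes to 0.96. Thinning moved thyroid genes to 99.1, the level trend integrins to 98.1 and the length trend the endoplasmic reticulum list to 3.39. Matching on length moved integrins to 98.0, and omission of shared genes to 98.7. For floors and omissions the membership differs by construction, and otherwise the cause was not tested. At this depth, genes below about 0.4 TPM rest on 3 reads or fewer in a gene of 2000 bases, and short RNAs on few reads at any TPM.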

Other observations

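The tests of growth state and of the difference between the mitochondrial rRNAs, and the scan of gene families, were chosen after the results were seen. Those of gene length, RNAs without poly(A) tails, STAT3 genes and alpha-arrestins were set before their own outcomes were known. They too were prompted by patterns already seen in these data. The genes named in this part were chosen after their values were seen, apart from IL1A and IL1B, which the rule takes.

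A scan covered 181 families of protein-coding genes with the same symbol stem and at least 8 expressed members. It placed 16 above and 15 below the limits. By chance 9.1 in all would be outside if genes varied independently, which members of 1 family may not. The highest included the MCM genes (median 1.21, most of them replication helicase subunits already in the list above) and semaphorins (SEMA, median 0.94, 7 of 13 at least 1.5-fold higher and 3 lower). Also among them were the GALNT enzymes that start mucin-type glycosylation (median 0.95, 7 of 11 higher and 1 lower) and aldehyde dehydrogenases (ALDH, median 0.84, 7 of 13 higher and 1 lower). Frizzled receptors (FZD, median 0.78, 5 of 8 higher and 1 lower) and kinesins (KIF, median 0.57, 14 of 29 higher and 1 lower) were there too. Kinesins overlap the mitosis list above, which holds KIF20A. The lowest included Kruppel-like factors (KLF, median -0.56, 5 of 13 lower and 0 higher), dual-specificity phosphatases (DUSP, median -0.39, 7 of 17 lower and 2 higher) and keratins (KRT, median -0.42, 4 of 11 lower). A placement outside the limits can go with a small difference. The ZNF genes had the lowest percentile (0.0), but a median of only -0.05, with 39 of 348 higher and 29 lower. The NBPF genes (median -0.66, 7 of 10 lower) are near-identical copies, so their values depend on how shared reads were counted.

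The inflammatory, ATF4 and ERK groups stood below control while replication genes stood above, with 3.21 on the log2 scale between the NF-kB and replication medians. A gene length trend between the libraries is argued against, since removing it took away 2.2% of the distance. What stays open is whether the pattern follows from loss of XPR1, from other targets of the siRNA, whose sequence is not given in the sources used here, or from a different growth state of the 2 cultures. With 1 control library these cannot be told apart. Without a library of untransfected cells, it also cannot be told which of the 2 libraries departs from the untreated state.

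SAA1 (850.1 and 5212 TPM) and SAA2 (36.1 and 313.1 TPM), acute-phase serum amyloid genes that respond to inflammatory cytokines, were 6.13-fold and 8.68-fold higher in the library where IL1A, IL1B and IL6 were lower. These genes are near-identical, so the split of reads between them is uncertain, and the sum over the SAA genes was 6.21-fold higher. A wider STAT3 acute-phase response is a hypothesis that was not borne out. The median of 24 expressed STAT3 acute-phase genes other than SAA was -0.27, at percentile 1.0, with 5 higher and 8 lower. Genes looked at one by one went both ways. SOCS3 was 208.4 and 87.6 TPM and LCN2 744.9 and 543.4 TPM, while C3 was 924.7 and 1882 TPM and STAT3 itself 84.9 and 108.5 TPM. A biological cause specific to the SAA genes was not tested.

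The 12S rRNA of the mitochondrion, MT-RNR1, was 15640 and 7095 TPM, 2.204-fold lower (2.17 to 2.24), while the 16S rRNA, MT-RNR2, was 1.23-fold lower (1.22 to 1.24). The 13 mitochondrial mRNAs lay between -0.27 and 0.36 on the log2 scale. Less carry-over of RNA without poly(A) tails was predicted to lower both rRNAs alike. A difference of -0.84 between their log2 ratios argues against such an equal loss as the whole cause. Whether both rRNAs are carried over at the same rate was not checked. Whether less carry-over made a part of the difference stays open. The median of 43 genes annotated as small nuclear, nucleolar and related RNAs was -0.04, with a bootstrap interval of -0.57 to 0.30. These genes include U6 pseudogenes, and each had at most 33 reads in a library, so they measure carry-over poorly. Mitochondrial tRNAs had a median of -0.23, with 13 of 18 below 0.

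TXNIP (47.1 and 312.4 TPM) and ARRDC4 (3.09 and 33.9 TPM), glucose-responsive alpha-arrestins, were 6.63-fold and 10.96-fold higher. A wider rise of the alpha-arrestin family was set as a hypothesis and was not borne out, since the 3 other expressed members had a median of -0.51.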
